A study of Mus musculus with 3 samples.

How the data were processed

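Single-cell RNA was measured in 3 libraries from the calvaria, the roof of the skull, of C57BL/6 mice aged 8 weeks. The control library came from a calvaria without tumour. The scratch-negative library came from a calvaria onto which HNM007 cells, a mouse squamous cell carcinoma line, had been implanted with the bone surface left intact. For the scratch-positive library the bone surface was first scratched with a needle, which removes the periosteum, the connective tissue sheath of bone. Tissue was taken 1 week after implantation, the tumour mass was cut away, and live CD45-positive and CD45-negative cells were mixed in equal numbers before loading, per the labels' protocols. CD45, encoded by Ptprc, marks immune cells. Each group had 1 library.

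The deposited values were counts of unique molecular identifiers (UMIs), raw molecule counts per gene and cell barcode, in matrices already limited to called cells. They were made with Cell Ranger 6.1.2, per the file headers, and Cell Ranger with the mouse build mm10 is also named in the submitters' processing notes. The tables listed 31053 genes. The control library held 7490 barcodes and 100089008 UMIs, the scratch-negative library 8517 barcodes and 167623741 UMIs, and the scratch-positive library 9504 barcodes and 395654008 UMIs. Gene positions were taken from GENCODE annotation of GRCm38, the assembly that mm10 names.

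Everything after the deposited counts was computed here. Barcodes were kept with at least 500 detected genes and at most 10% mitochondrial UMIs. Those below the gene minimum numbered 887, 325 and 335 in the control, scratch-negative and scratch-positive libraries, and 77, 125 and 204 exceeded the mitochondrial limit. Scrublet was run per library with an expected rate of 0.06. Its own threshold marked 7, 2 and 643 barcodes, which for the control (0.093%) and scratch-negative (0.023%) libraries is too few to be a working call. Barcodes with the highest Scrublet scores were therefore removed at a rate of 0.8% per 1000 barcodes, 449, 580 and 723 of them, and Scrublet's own calls became an alternative. This left 6181, 7584 and 8424 cells with medians of 8871, 11258 and 36353 UMIs.

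Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were scaled with a maximum of 10 and reduced to 30 principal components. A graph of 15 neighbours was divided by Leiden clustering at resolution 1.0 in scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9). The 3 libraries were clustered together without batch correction, because library and group are the same here. Clusters were named from marker lists. A name required at least 3 detected markers, each with a UMI in at least 20% of the cells and at least 1.5 times the level of the other clusters. A cluster stayed unnamed where its leading genes or its depth went against the name. After the clusters had been seen, a further rule left a cluster unnamed where a UMI of Ptprc in more or fewer than 50% of its cells went against the class. That rule applied to cluster 13, which held 0, 0 and 41 cells. Of 28 clusters, 4 stayed unnamed. No cluster met the rule for endothelial cells, so no values are given for them.

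Shares of cells are given within the immune or the non-immune compartment, since the CD45 mixing sets the balance between them. Red cell and platelet clusters are in neither. Shares carry exact Clopper-Pearson 95% intervals, and for a share of 0 the upper limit is given as 3 counts of the total. For expression, UMIs were summed per library and class and divided by the class total, as CPM. Levels carry exact Poisson intervals and ratios of 2 libraries exact conditional binomial intervals. All of these intervals cover counting error only. Where a library held 0 UMIs the fold is a lower bound against a floor of 3 UMIs in that library. A pair of libraries was compared in a class with at least 50 cells in both. The fibroblast/periosteal class was also compared with control at 48 control cells, a minimum of 40 set after the cell numbers were known. With 1 library per group no test between groups exists and no p-value is given.

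Gene lists were summarised by the median log2 ratio of their members, with 0.5 UMI scaled to library size added on both sides and members needing 10 UMIs in the 2 libraries together. A member counted as higher or lower when its ratio was at least 1.5-fold and its whole counting interval lay on the same side of 1. Each median is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The lists covered TIMPs and metalloproteinases, hypoxia and glycolysis, collagens and matrix, TGF-beta response and contractile genes, inflammatory stroma, osteoclast-regulating cytokines, progenitor and quiescent fibroblast genes, osteoblast differentiation, osteoclast genes, interferon response, MHC class II, proliferation, tumour-associated macrophage genes, inflammatory myeloid genes, neutrophil granules, neutrophil activation, cytotoxic lymphocyte genes, T-cell checkpoint and regulatory genes, and dissociation and stress genes. The interferon list in NK cells and the lists in tumour cells were added after the first results.

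Genes are named by rule. Per pair these were the 6 highest and 6 lowest ratios in the fibroblast/periosteal class and the 2 highest and 2 lowest in osteoblast-lineage cells, monocytes/macrophages and neutrophils. A gene needed 50 CPM and 30 UMIs in the higher library, an interval beyond 1.5-fold, and at least 10% of the level of the named class where it was highest, as a guard against free RNA. Unnamed clusters did not count for this level, nor for the percentages of the highest class given below. Mitochondrial, ribosomal protein, haemoglobin, antigen receptor and sex-linked marker genes and predicted genes were left out. A fixed set of genes of matrix turnover, osteoclast control, contraction and angiogenesis was always named in fibroblasts, with members of each list, which did not need the 10% guard. Of the genes picked by these rules, 2 are not reported here. The filters, markers, lists, naming rule and most alternatives were fixed before the data were examined.

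The ratio and list calculations were tested on simulated data with the totals of the fibroblast/periosteal class of the 2 tumour libraries. The simulated counts were independent Poisson draws, the model behind the intervals, without variation between cells. The values that follow therefore check the calculation and not the spread of real data. Intervals held the true ratio for 96.0% of 11486 genes. The rule of size recovered 100% of genes set at 0.25, 96.0% at 0.5, 98.0% at 2 and 100% at 4 times, of 50 genes each, and took up 0.815% of 11286 unchanged genes. Of 40 lists of unchanged genes, 2 fell under percentile 5 or over 95.

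Alternatives changed 1 choice at a time: the gene minimum (200 or 1000), the mitochondrial limit (5% or 20%), doublet removal, the Leiden resolution (2.0), a class per cell by marker score, TMM factors from edgeR 4.0.16 (R 4.3.3), a total without mitochondrial, ribosomal and haemoglobin genes, a mean over cells, cells thinned to 2000 UMIs, the list minimum (none or 100 UMIs), an added 5 UMIs, fibroblasts and osteoblasts joined, and all kept cells as denominator. Scrublet's own calls, single clusters of a class, neutrophil clusters with equal weight, unnamed clusters counted as the neutrophils they match best, cells without a Ptprc UMI, and names kept against Ptprc were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.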

Results

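The data describe the cells of mouse calvaria without tumour, under a carcinoma implanted on intact bone, and under a carcinoma implanted on bone stripped of its periosteum. The second state precedes bone invasion and the third is invasive. The design asks how the stroma and immune cells at the bone surface differ when a tumour meets the periosteum and when the periosteum is missing. After filtering, 22189 cells remained from 25511 barcodes. Depth differed between the libraries. The median cell held 8871 UMIs and 1669 genes in control, 11258 UMIs and 1895.5 genes in scratch-negative, and 36353 UMIs and 5065 genes in scratch-positive. There were no replicates, so each difference below is between 2 libraries, with no estimate of the spread between mice. No library came from scratched bone without tumour. Effects of the scratch itself, of the missing periosteum and of invasion therefore cannot be told apart in scratch-positive.

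Osteoclast-like cells were named by genes of osteoclasts, the multinucleated cells that resorb bone, but whether they had fused or were precursors was not measured. They made up 0.494% of immune cells in control (28 of 5671, 95% interval 0.328 to 0.713), 1.296% in scratch-negative (83 of 6406, 1.03 to 1.60) and 21.2% in scratch-positive (874 of 4118, 19.98 to 22.5). Monocytes/macrophages, which include osteoclast precursors, made up 6.59%, 10.4% and 19.2%. Neutrophils formed 70.4%, 60.4% and 31.3%, or 80.1%, 76.7% and 49.9% with clusters 2 and 6, which stayed unnamed but match neutrophils best, counted among them. Dendritic-like cells were at 0.106%, 0.624% and 2.94%. B-lineage cells (4.32%, 2.45% and 0.777%) and T cells (1.80%, 1.14% and 0.413%) were lowest in scratch-positive, while NK-like cells were at 2.91%, 2.03% and 2.26% and granulocyte-monocyte progenitors at 3.69%, 5.32% and 3.35%. Among osteoclasts and monocytes/macrophages together, osteoclasts were 6.97%, 11.1% and 52.6%. The cells had been mixed for CD45 in equal numbers, yet immune cells were 91.7%, 84.5% and 48.9% of those kept. The scratch-positive library was the deepest over all cells, but not within each class. Median UMIs in scratch-negative and scratch-positive were 8937 and 7420 in neutrophils, 29813.5 and 28576.5 in fibroblasts, 71729 and 64274.5 in tumour cells, and 40336 and 36232.5 in osteoclasts. In monocytes/macrophages they were 14603.5 and 21827. With all kept cells as denominator the osteoclast share in scratch-positive was 10.4%.

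Cells of the epithelial class, named by keratins and other epithelial markers and called tumour cells here, remained after the tumour had been cut away. They were 0 of 207 non-immune cells in control, which allows a share of up to 1.45%, 21.2% in scratch-negative (201 of 946, 18.7 to 24.0) and 84.4% in scratch-positive (3620 of 4287, 83.3 to 85.5). Without them, fibroblast/periosteal cells made up 23.2% (17.6 to 29.5), 72.8% (69.4 to 75.9) and 63.3% (59.5 to 66.9) of non-immune cells. Cells named osteoblast-lineage, the lineage that forms bone, made up 29.0%, 9.53% and 2.25%, and chondrocyte-like cells 34.3% (71 cells), 0 of 745 cells (up to 0.403%) and 0.150% (1 cell). The 10 leading genes of the osteoblast-lineage class held 3 of its own markers. They also held Cxcl12 and Adipoq, markers used for reticular cells of the marrow, so such cells are not excluded from this class. Meningeal-like cells were at 2.90%, 2.68% and 1.20%. The chondrocyte-like cells of control lay close to the gene minimum, with medians of 949 UMIs and 549 genes. With a minimum of 1000 genes 0% of non-immune control cells were chondrocyte-like, 42.1% were fibroblast/periosteal and 51.8% osteoblast-lineage. With a minimum of 200 genes the tumour cell shares were 5.14% and 67.5%. Cluster 23, which held 148 of the 201 scratch-negative tumour cells, had the least evidence for its name. It had 3 detected epithelial markers and 0 among its 10 leading genes, and 24.0% of its cells had a UMI of Ptprc. Among unnamed clusters, cluster 2, led by the chemokine genes Ccl4, Ccl3 and Cxcl2, held 0.194%, 6.74% and 11.3% of immune cells, and cluster 6, led by histone genes, 9.49%, 9.55% and 7.33%. The shallow cluster 22 held 10.6%, 11.8% and 4.20% of non-immune cells with tumour cells included (22, 112 and 180 cells). Cluster 13, led by Gzmd, Ctsg and Mpo, held 0%, 0% and 0.956% (41 cells in scratch-positive). It was kept out of the granulocyte-monocyte progenitors because 24.4% of its cells had a UMI of Ptprc. Non-immune cells without tumour cells numbered 207, 745 and 667, and on that denominator the share of cluster 22 was highest in scratch-positive. Both clusters are in the denominator of the shares without tumour cells above.

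**Figure D1:**
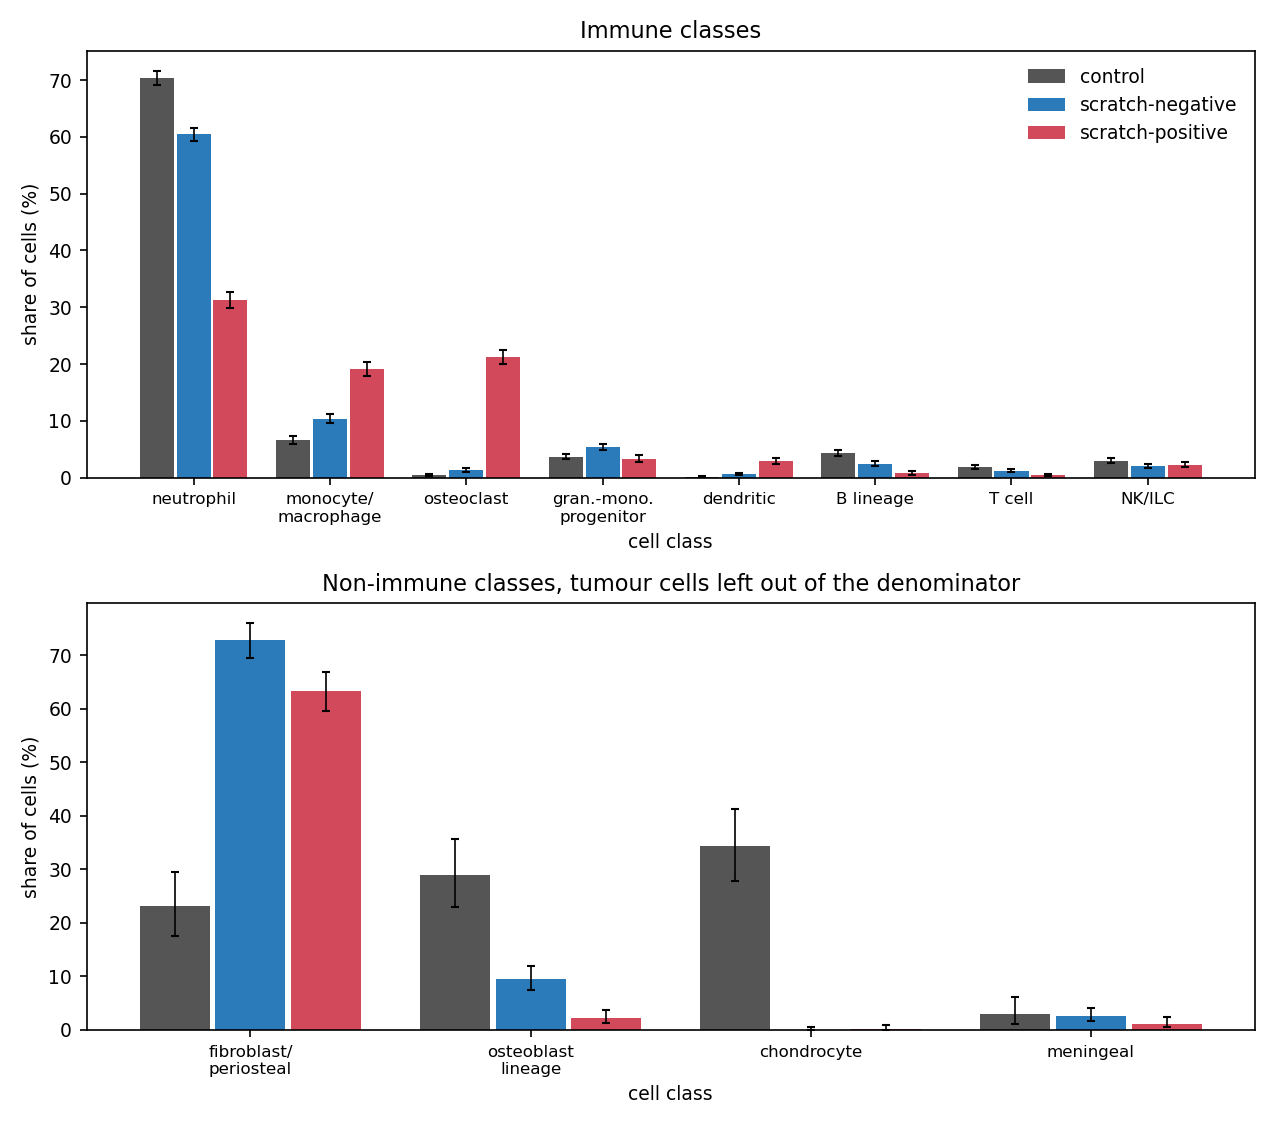
Bars show the share of immune cells (top) and of non-immune cells without tumour cells (bottom) in each class, in percent, for the control, scratch-negative and scratch-positive libraries; error bars are exact 95% intervals for counting error. Osteoclasts were 0.494%, 1.296% and 21.2% of immune cells.

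Transcripts of other classes were counted in neutrophils and fibroblasts. Krt8, a keratin of the tumour cells (911 CPM there in scratch-negative and 1342 in scratch-positive), was at 0, 1.62 and 30.4 CPM in neutrophils and at 0, 5.93 and 47.3 in fibroblasts of the control, scratch-negative and scratch-positive libraries. The neutrophil gene S100a8 was at 12999, 12132 and 1416 in fibroblasts. Ctsk, the collagen-degrading protease of osteoclasts, was at 0.969, 3.755 and 47.4 in neutrophils.

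The first comparison asks how the stroma under a tumour on intact bone differs from tumour-free stroma. Fibroblast/periosteal cells of scratch-negative carried 26.4-fold more Timp1 (21.9 to 32.1), at 5391 CPM against 204 in control. Timp1 (ENSMUSG00000001131), which encodes a secreted inhibitor of matrix metalloproteinases, lies on the plus strand of chromosome X at 20870166 to 20874735 in GRCm38. The highest ratios were of genes at 0 UMIs in control. Saa3, a serum amyloid gene (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700, minus strand), was at 709 CPM, at least 126-fold higher. Ddah1, whose product breaks down an inhibitor of nitric oxide synthases, was at least 45.7-fold higher, and Nos2, the inducible nitric oxide synthase, at least 27.4-fold. Serpinb2, an inhibitor of plasminogen activators, was at least 36.0-fold higher, Ereg, a ligand of the EGF receptor, at least 15.6-fold, and Hs6st2, a heparan sulphate sulphotransferase, at least 13.9-fold. The lowest ratios were those of Mrgprg, a Mas-related receptor gene (4 against 149 UMIs, 1190-fold lower, 455 to 4426), Smpd3, a sphingomyelinase needed for bone mineralisation (181-fold lower, 140 to 236), Akr1c18 (107-fold, 49.3 to 255), Krtdap (66.1-fold), Daglb (26.2-fold) and Cpe (25.6-fold).

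Of 20 hypoxia and glycolysis genes, 19 were higher and 0 lower in these fibroblasts, with a median log2 ratio of 2.23 (percentile 100). Vegfa, the angiogenic growth factor, was 7.49-fold higher (5.07 to 11.6), and Egln3 and Car9, both induced by low oxygen, were at least 11.7-fold and 8.36-fold higher. The inflammatory stroma list had 15 of 18 members higher and 1 lower (median 3.36, percentile 100), among them Lif, a cytokine at least 7.75-fold higher. Interferon response genes were higher in 13 of 20 (median 2.01, percentile 100), with Rsad2 (9.32% of its level in the highest class) at least 2.65-fold and Ifi44 at least 1.83-fold higher. Proliferation genes were higher in 13 of 18 (median 1.47, percentile 100), including the mitotic genes Ube2c (at least 12.8-fold) and Ccnb2 (at least 6.72-fold). TGF-beta response and contractile genes were higher in 10 of 16 and lower in 2 (median 0.94, percentile 100), among them Cnn1, calponin, at least 1.54-fold, and Acta2, smooth muscle actin, 3.88-fold (3.30 to 4.59). Of the osteoclast-regulating cytokines, 6 of 15 were higher and 2 lower (median 1.05, percentile 100). Tnfsf11, which encodes the osteoclast differentiation factor RANKL, had a ratio of 1.17 (0.608 to 2.58), and its decoy receptor gene Tnfrsf11b one of 3.68 (1.01 to 30.5).

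Genes of resting and bone-forming stroma were lower. The progenitor and quiescent fibroblast list had 12 of 14 members lower and 1 higher (median -2.20, percentile 0), with Clec3b 9.94-fold and Sfrp4 9.54-fold lower. Osteoblast differentiation genes were lower in 8 of 13 and higher in 2 (median -2.26, percentile 0), with the osteocalcin genes Bglap2 and Bglap 19.5-fold and 14.7-fold lower, though in control they were at 4.37% and 1.76% of their level in the highest class. Collagens and matrix had 11 of 24 lower and 5 higher (median -0.45, percentile 0.08). Postn (periostin) was 3.24-fold lower and Aspn 7.39-fold lower, Lox, a collagen cross-linking enzyme, 13.005-fold higher, and Col1a1 at 21833 against 25452 CPM. Of TIMPs and metalloproteinases 3 of 17 were higher and 4 lower (median -0.33, percentile 7.13). Timp2 was 4.25-fold lower, Timp3 had a ratio of 0.967 (0.846 to 1.11), Mmp13 was 4.05-fold lower, Mmp14 1.59-fold lower and Mmp3 4.38-fold higher. Dissociation and stress genes had a median of 0.25 (percentile 60.7, 2 of 14 higher and 1 lower), with Fosb 2.22-fold and Hspa1a 1.81-fold higher. All 48 control fibroblasts belonged to cluster 12, whereas 349 of the 542 scratch-negative ones belonged to cluster 27, which had no control cell. Within cluster 12 alone the log2 ratio of Timp1 was 1.69 in place of 4.72, the hypoxia median was 0.13, and Mmp13 turned to higher than in control. At Leiden resolution 2.0, in the finer cluster with all 48 control cells, Acta2 was at 500 CPM in scratch-negative (193 cells) against 279 in control. Saa3 was at 113 CPM there in scratch-negative, in place of 709 over the class.

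Monocytes/macrophages of scratch-negative carried Arg1, the arginase of alternatively activated macrophages, at 228 CPM against 0 UMIs in control, at least 514-fold higher. Cxcl3, a neutrophil-attracting chemokine gene, was 126-fold higher (71.8 to 243), while Hpgd, which inactivates prostaglandins, was 4.11-fold lower and F13a1, a coagulation factor gene of monocytes, 3.26-fold lower. Interferon genes were higher in 15 of 20 (median 1.33, percentile 100), with Iigp1 26.5-fold and Gbp2 20.5-fold higher. Inflammatory myeloid genes were higher in 15 of 17 (median 2.27, percentile 100), and osteoclast-regulating cytokines in 8 of 9 (median 1.83, percentile 100), with Il1a 8.68-fold and Csf1 7.78-fold higher. MHC class II genes were higher in 6 of 7 (median 0.89, percentile 100), with H2-DMb1 2.26-fold and H2-Ab1 2.24-fold. The median was 0.60 for hypoxia and glycolysis (10 of 20 higher, percentile 100), 0.49 for tumour-associated macrophage genes (6 of 17 higher and 1 lower, percentile 100), 0.97 for osteoclast genes (4 of 10 higher and 1 lower, percentile 100), -0.22 for proliferation (0 of 18 beyond the size rule, percentile 3.13) and 0.29 for dissociation and stress (3 of 14 higher, percentile 99.7). Cluster 14 held 268 of the 374 control cells of this class and cluster 18 held 533 of the 666 scratch-negative ones. Within cluster 14 alone Arg1 had a log2 ratio of 1.996, against 12.37 over both clusters. Within cluster 18 alone F13a1 turned to higher than in control.

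In neutrophils of scratch-negative, Wfdc17, an inhibitor gene of the whey acidic protein family, was 9.60-fold higher (9.06 to 10.2) and Ifitm1, an interferon-induced gene, 6.17-fold higher, and Ccl6 and Vps37b were 2.20-fold and 2.10-fold lower. Inflammatory myeloid genes were higher in 10 of 17 (median 1.15, percentile 100). Medians were near 0 for hypoxia and glycolysis (0.13, percentile 99.8, 4 of 20 higher and 1 lower), interferon response (0.12, percentile 99.5, 5 of 19 higher), neutrophil granules (0.01, percentile 85.5, 1 of 13 higher and 1 lower), neutrophil activation (-0.17, percentile 35.8, 2 of 13 lower), dissociation and stress (0.01, percentile 90.8, 2 of 14 higher and 1 lower) and proliferation (0.24, percentile 100, 1 of 18 higher). The 6 neutrophil clusters were not in the same balance in the 3 libraries. With equal weight per cluster the medians of proliferation and activation were -0.23 and 0.07, and with clusters 2 and 6 counted as neutrophils those of inflammatory myeloid, interferon and activation genes were 2.68, 1.17 and 0.79, though inflammatory genes lead cluster 2. Cxcr4, the receptor that retains neutrophils in marrow, was 1.70-fold lower. In T cells of scratch-negative Gzmb, granzyme B, was 57.1-fold higher on 396 against 10 UMIs, while Eomes was 4.68-fold lower on 4 against 27 UMIs and Ccl5 had a ratio of 0.941. Of 12 cytotoxic genes 5 were higher and 1 lower (median 0.52, percentile 99.9). Checkpoint and regulatory genes were higher in 6 of 10 and lower in 1 (median 0.79, percentile 100), with Tnfrsf9 7.16-fold and Ctla4 6.21-fold. Interferon genes in T cells were higher in 8 of 14 (median 0.92, percentile 100), with Isg15 3.78-fold, and proliferation genes in 9 of 18 (median 1.07, percentile 100), and the dissociation and stress median was 0.24 (3 of 14 higher, percentile 85.6). B-lineage cells had medians of 0.21 for interferon genes (3 of 17 higher, percentile 97.7), 0.19 for proliferation (0 of 18 beyond the size rule, percentile 99.8) and -0.23 for dissociation and stress (2 of 14 lower, percentile 1.28). NK-like cells had Gzmb 7.49-fold and Isg15 3.61-fold higher, with a median of 0.39 for cytotoxic genes (3 of 13 higher, percentile 100) and 1.12 for interferon genes (9 of 18 higher, percentile 100).

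Osteoblast-lineage cells, a class that may include reticular cells of the marrow, could be compared only between scratch-negative (71 cells) and control (60 cells). Proliferation genes were higher in 14 of 18 (median 1.38, percentile 100), with the cyclin gene Ccna2 12.3-fold higher on 45 against 2 UMIs. Ccl4 (561 against 0 UMIs, at least 102-fold) and Ccl3 (188 against 1 UMI, ratio 103, 18.2 to 4084), chemokines of myeloid cells, had the highest ratios, and S100a8 was at 20268 CPM against 6951 in these cells. Both chemokine genes lead the unnamed cluster 2, which the guard against free RNA did not count. Over the 3 libraries 19.2% of osteoblast-lineage cells had a UMI of Ptprc, so RNA of myeloid cells is not excluded for Ccl4 and Ccl3. Ms4a4d was 7.49-fold lower and Fst, follistatin, an activin antagonist, 5.72-fold lower. Osteoblast differentiation genes had a median of -0.01 (4 of 16 higher and 4 lower, percentile 72.7), with Sost, sclerostin, at least 7.11-fold and Bglap3 2.56-fold higher. Medians were 0.14 for collagens and matrix (1 of 22 higher and 3 lower, percentile 99.0), -0.16 for TIMPs and metalloproteinases (1 of 17 higher and 3 lower, percentile 43.3), 0.21 for hypoxia and glycolysis (3 of 17 higher and 1 lower, percentile 99.4), -0.40 for osteoclast-regulating cytokines (2 of 11 higher and 4 lower, percentile 12.5) and -0.41 for dissociation and stress (2 of 14 higher and 3 lower, percentile 1.695). Col3a1 was 4.16-fold higher at 3.97% of its level in the highest class, Ogn 3.97-fold lower, Adamts1 2.25-fold lower and Mmp13 1.82-fold lower. With a class given to each cell by marker score, Fst and the medians of collagens and of dissociation and stress turned direction, to log2 values of 0.85, -0.0831 and 0.0977.

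The second comparison sets the stroma of the invasive lesion, where the periosteum was stripped, against tumour-free stroma. Timp1 was 13.4-fold higher (11.1 to 16.4), at 2745 CPM, and Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590, minus strand) was 18.5-fold higher (15.8 to 21.9), at 5181. The highest ratios were of granzyme genes, proteases usually made by cytotoxic lymphocytes. Gzme was at 985 CPM (at least 175-fold higher), Gzmd at 826 (at least 147-fold) and Gzmc at 390 (at least 69.3-fold). These granzymes are close paralogs, so the split of UMIs among them is uncertain. Ddah1 was at least 49.4-fold, Saa3 at least 31.9-fold and Col7a1, the collagen of anchoring fibrils, at least 31.7-fold higher. The lowest ratios were of Mrgprg (0 against 149 UMIs, at least 1161-fold lower), Smpd3 (3 against 402 UMIs, 3132-fold lower, 1064 to 15251), Krtdap (0 against 60, at least 467-fold), Cxcl13 (1 against 33, 771-fold, 129 to 31377), Akr1c18 (117-fold) and Dlk1, a Notch pathway ligand of progenitors (70.1-fold, 35.7 to 148).

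TGF-beta response and contractile genes were higher in 12 of 16 and lower in 2 (median 1.25, percentile 100), with Cnn1 at least 21.5-fold and Tagln, transgelin, 19.98-fold higher. Proliferation genes were higher in 16 of 18 (median 2.09, percentile 100), with Ube2c at least 23.9-fold and Ccnb2 at least 12.3-fold. Osteoclast-regulating cytokines were higher in 8 of 15 and lower in 2 (median 1.48, percentile 100). Tnfsf11 (ENSMUSG00000022015, chromosome 14, 78277445 to 78308043, minus strand) was 3.90-fold higher (2.04 to 8.56), at 65.8 against 16.9 CPM, Tnfrsf11b had a ratio of 2.82 (0.766 to 23.6), and Il11 and Lif were at least 3.55-fold and 3.52-fold higher. Inflammatory stroma genes were higher in 11 of 18 and lower in 4 (median 2.91, percentile 100). Hypoxia and glycolysis genes were higher in 11 of 20 and lower in 2 (median 0.87, percentile 100), with Vegfa 1.57-fold higher (1.05 to 2.43). Interferon genes went both ways, 5 of 20 higher and 3 lower (median 0.21, percentile 68.7), with the chemokine gene Cxcl10 43.2-fold higher on 4 control UMIs and Ifi27l2a 6.94-fold lower.

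All 14 progenitor and quiescent fibroblast genes were lower (median -3.90, percentile 0), with Clec3b 62.4-fold and Pi16 44.3-fold. Osteoblast differentiation genes were lower in 9 of 13 and higher in 2 (median -3.32, percentile 0), with Bglap2 35.5-fold and Bglap 28.2-fold. As stated for the first comparison, both were in control fibroblasts at a small part of their level in the highest class. RNA of other cells is therefore not excluded for them. Collagens and matrix were lower in 13 of 24 and higher in 5 (median -0.67, percentile 0.02), with Dcn, decorin, 9.57-fold, Ogn 9.45-fold, Postn 3.67-fold and Col1a1 1.66-fold lower. TIMPs and metalloproteinases were lower in 9 of 18 and higher in 3 (median -0.63, percentile 0.78). Timp2 was 3.51-fold lower, Timp3 2.73-fold lower, Mmp13 1.59-fold lower, Mmp14 had a ratio of 0.934 (0.824 to 1.06), and Mmp10 was at least 3.57-fold higher. Dissociation and stress genes were lower in 5 of 14 (median -0.37, percentile 1.38), with Atf3 2.97-fold and Fos 1.97-fold lower. Of the 422 scratch-positive fibroblasts 312 belonged to cluster 27. Within cluster 12 alone Timp1 had a log2 ratio of 2.68 in place of 3.75, and Gzmd one of 1.81 in place of 13.39. There Mmp13, Fos and the stress median turned to higher and Vegfa to lower than in control. With osteoblasts joined Vegfa and Cxcl10 turned to lower. At Leiden resolution 2.0, in the finer cluster with all 48 control cells, Acta2 was at 1588 CPM in scratch-positive (110 cells) against 279 in control. It was at 6609 in 268 other scratch-positive cells.

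Monocytes/macrophages of scratch-positive carried Arg1 at 358 CPM, at least 805-fold above control, and Ccl12, a monocyte-attracting chemokine gene, with a ratio of 1514 on 1 control UMI (272 to 59809). Hpgd was 8.67-fold and the histone gene Hist1h2ap 6.48-fold lower. Osteoclast genes were higher in 9 of 11 and lower in 1 (median 4.30, percentile 100), with Ctsk 89.2-fold and Atp6v0d2, a proton pump subunit of osteoclasts, 66.2-fold higher. Ctsk and Atp6v0d2 were at 1.85% and 2.35% of their level in the highest class, and Ctsk was at 198 CPM in this class and at 47.4 in neutrophils of the same library. Inflammatory myeloid genes were higher in 16 of 17 (median 3.03, percentile 100), with Cxcl3 255-fold and Cxcl2 37.7-fold. Osteoclast-regulating cytokines were higher in 10 of 11 (median 3.03, percentile 100). MHC class II genes were higher in 6 of 7 (median 1.42, percentile 99.9), with H2-DMb1 4.54-fold and H2-Ab1 3.29-fold, and tumour-associated macrophage genes in 10 of 17, with 2 lower (median 1.12, percentile 100), with Spp1, osteopontin, 28.6-fold. The median was 1.04 for hypoxia and glycolysis (13 of 19 higher, percentile 100), -0.15 for interferon genes (6 of 20 higher and 7 lower, percentile 2.87), 0.26 for proliferation (4 of 18 higher, percentile 62.1) and 0.20 for dissociation and stress (5 of 14 higher and 4 lower, percentile 46.0). Cluster 18 held 732 of the 789 scratch-positive cells and 106 of the 374 control cells. Within cluster 14 alone the medians of osteoclast genes and MHC class II turned to -0.25 and -1.30.

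In neutrophils of scratch-positive, Cxcl3 was 21.5-fold (18.03 to 25.9) and Lipg, endothelial lipase, 20.6-fold higher than in control, and Jaml, an adhesion molecule gene, was 3.88-fold lower. Cxcr4 was 2.92-fold lower. Proliferation genes were higher in 12 of 18 (median 0.78, percentile 100) and inflammatory myeloid genes in 9 of 17, with 3 lower (median 0.75, percentile 100). The median was 0.38 for hypoxia and glycolysis (6 of 19 higher and 2 lower, percentile 99.4), -0.28 for interferon genes (8 of 18 lower and 2 higher, percentile 11.4), -0.11 for granules (2 of 13 higher and 2 lower, percentile 24.6), -0.41 for activation (6 of 14 lower and 1 higher, percentile 2.87) and 0.05 for dissociation and stress (1 of 14 higher and 2 lower, percentile 67.5). With equal weight per neutrophil cluster the medians of proliferation, inflammatory myeloid, interferon and activation genes were 0.27, 1.71, 0.15 and 0.07, and with clusters 2 and 6 counted as neutrophils they were 0.38, 2.92, 0.74 and 1.43. In NK-like cells the members went both ways, with a median of -0.02 for cytotoxic genes (1 of 12 higher and 2 lower, percentile 14.8) and for interferon genes (3 of 12 higher and 2 lower, percentile 37.0). Gzmb was 4.51-fold higher, Ifng, interferon gamma, 3.41-fold lower on 9 against 77 UMIs and Isg15 3.36-fold lower on 7 against 59 UMIs. With a class given to each cell by marker score Isg15 turned to higher than in control.

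**Figure D2:**
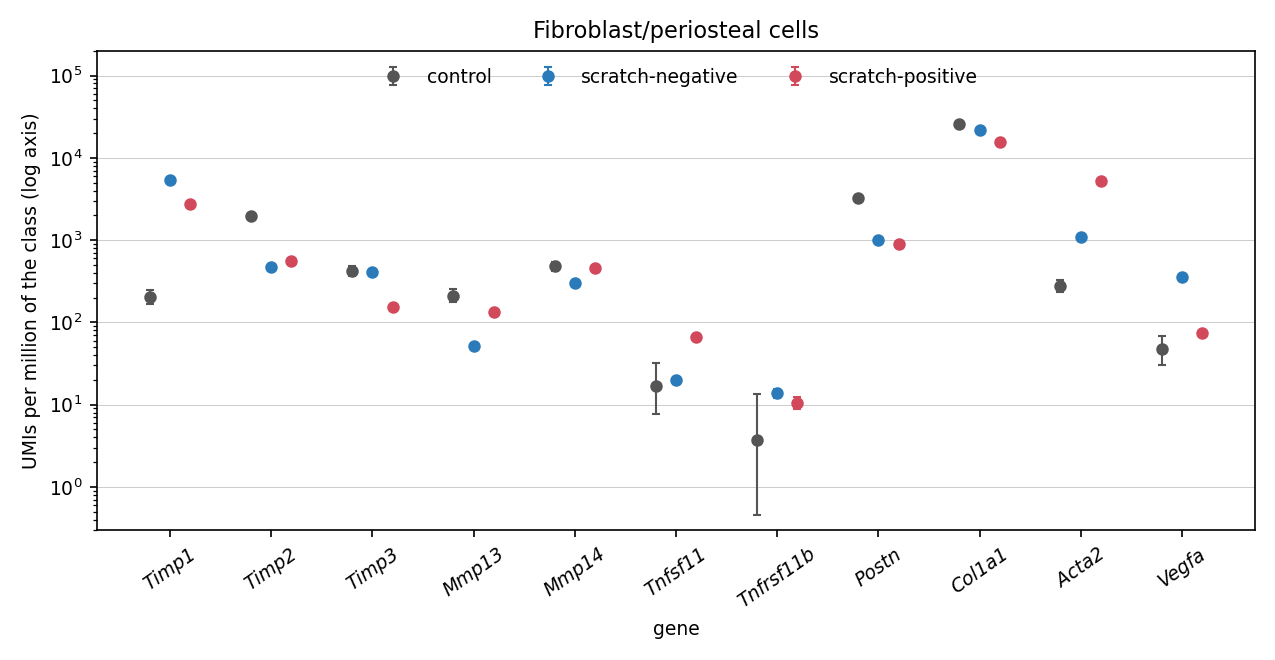
Points show CPM (log axis) of 11 genes in fibroblast/periosteal cells of the 3 libraries, with exact Poisson 95% intervals for counting error. Timp1 was at 204, 5391 and 2745 in control, scratch-negative and scratch-positive, and Acta2 at 279, 1083 and 5181.

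The third comparison sets the invasive lesion against the lesion with the periosteum in place. In the fibroblast/periosteal class of scratch-positive Acta2, Gzmd, Gzmc and Gzme were higher, and whether the cells that carry most of them are fibroblasts was not settled, while most members of the hypoxia, inflammatory stroma and interferon lists were lower. Acta2 was 4.78-fold higher (4.70 to 4.86), Cnn1 13.9-fold and Tagln 4.82-fold. Gzmd (ENSMUSG00000059256, chromosome 14, 56129556 to 56132608, minus strand) was 612-fold higher (408 to 966), Gzmc 85.1-fold and Gzme 84.8-fold. Col26a1, a collagen gene, was 165-fold higher, and Grem1, an antagonist of bone morphogenetic proteins, 48.8-fold. Mcpt8, a protease gene among the markers used for mast cells, basophils and eosinophils, was 48.5-fold higher. No cluster was named as such cells, so the guard against free RNA did not count them. In NK-like cells of scratch-positive Gzmd had 0 CPM. Timp1 was 1.96-fold lower (1.94 to 1.99), and Timp3 2.64-fold lower, while Timp2 had a ratio of 1.21 (1.17 to 1.25). Tnfsf11 was 3.34-fold higher (2.94 to 3.80) and Tnfrsf11b had a ratio of 0.768 (0.616 to 0.955). Mmp13, a collagenase, was 2.55-fold higher (2.35 to 2.77), Mmp14 had a ratio of 1.49 (1.43 to 1.54), Mmp10 was 42.7-fold higher on 8 scratch-negative UMIs, and Mmp3 was 3.85-fold lower. The lowest ratios were of Dmkn (37.1-fold lower, 26.4 to 53.7), Apln, apelin, a vascular peptide (20.2-fold), Nos2 (20.006-fold), Krt19 (17.6-fold), Adm, adrenomedullin (15.03-fold), and Mt2, metallothionein (11.5-fold).

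Hypoxia and glycolysis genes were lower in 17 of 20 and higher in 0 (median -1.45, percentile 0), with Vegfa 4.78-fold and Egln3 9.97-fold lower. Inflammatory stroma genes were lower in 13 of 18 and higher in 2 (median -1.61, percentile 0), with Ccl8 5.35-fold lower. Lcn2, lipocalin, was 4.99-fold lower at 7.06% of its level in the highest class, and the neutrophil gene S100a8 was at 12132 CPM in scratch-negative and 1416 in scratch-positive in the same fibroblasts. Interferon genes were lower in 14 of 20 and higher in 0 (median -1.36, percentile 0), with Rsad2 15.5-fold and Ifi27l2a 6.08-fold. All 14 progenitor and quiescent fibroblast genes were lower (median -1.76, percentile 0), with Dpp4 7.02-fold and Clec3b 6.28-fold. Collagens and matrix were lower in 8 of 24 and higher in 4 (median -0.32, percentile 0.02), with Col14a1 4.64-fold, Dcn 3.08-fold and Col1a1 1.42-fold lower, and Postn at a ratio of 0.882 (0.861 to 0.904). Proliferation genes were higher in 12 of 18 (median 0.78, percentile 100), with Stmn1 2.21-fold and Cdk1 2.11-fold. TGF-beta response and contractile genes were higher in 8 of 16 and lower in 4 (median 0.36, percentile 89.9). Osteoclast-regulating cytokines were lower in 8 of 15 and higher in 5 (median -0.61, percentile 0.03), with Osm, oncostatin M, 4.87-fold lower and Pthlh, the parathyroid hormone-related peptide gene, 3.78-fold higher. Osm was at 6.69% of its level in the highest class and Pthlh at 10.7%, and the tumour gene Krt8 was at 5.93 CPM in scratch-negative and 47.3 in scratch-positive in these fibroblasts, so RNA of neutrophils and tumour cells is not excluded for them. Osteoblast differentiation genes were lower in 5 of 13 and higher in 2 (median -0.48, percentile 0.69), with Bglap3 6.73-fold lower on 5 UMIs (0.215% of its level in the highest class) and Pdpn 2.16-fold lower. TIMPs and metalloproteinases were lower in 8 of 18 and higher in 2 (median -0.26, percentile 0.24), and dissociation and stress genes lower in 6 of 14 (median -0.54, percentile 0.01), with Fosb 2.22-fold and Dnajb1 2.19-fold.

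The direction of Timp1 and of the hypoxia list between the tumour libraries depended on which fibroblasts were compared. Within cluster 12 (193 and 110 cells) Timp1 had a log2 ratio of 0.99 and the hypoxia list a median of 0.19, and within cluster 27 (349 and 312 cells) these were -1.09 and -1.58. At Leiden resolution 2.0, 268 scratch-positive and 9 scratch-negative fibroblasts formed a cluster of their own that stayed unnamed. Without them the log2 ratio of Timp1 was -0.15, that of Acta2 0.64 and that of Gzmd 2.43, and Mmp10 turned to lower in scratch-positive. Whether these cells, at 6609 CPM of Acta2 and 1152 of Gzmd in scratch-positive, are fibroblasts or mural cells, the contractile cells of vessels, was not settled.

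**Figure D3:**
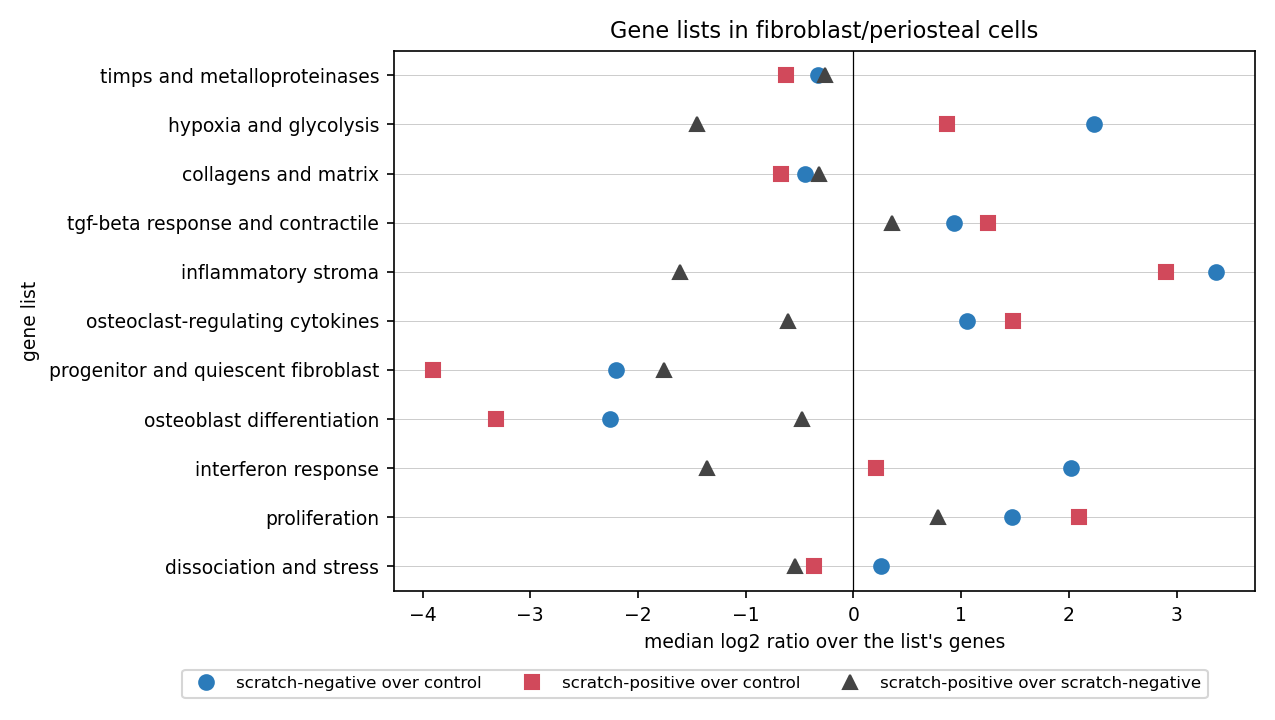
Points show the median log2 ratio (horizontal axis) of each gene list (vertical axis) in fibroblast/periosteal cells for the 3 pairs of libraries. The hypoxia and glycolysis median was 2.23 for scratch-negative over control, 0.87 for scratch-positive over control and -1.45 for scratch-positive over scratch-negative.

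In monocytes/macrophages of scratch-positive osteoclast genes were higher than in scratch-negative in 9 of 11 and lower in 2 (median 3.42, percentile 100), with Ctsk 58.0-fold and Atp6v0d2 26.7-fold, at 1.85% and 2.35% of their level in the highest class. Ctsk in neutrophils was at 3.755 and 47.4 CPM in the same libraries and osteoclasts numbered 83 and 874, so RNA of osteoclasts is not excluded. Hmgn1, a chromatin protein gene, was 7.58-fold (6.71 to 8.59) and Spint1, a protease inhibitor gene, 7.497-fold higher. Ifit2 and Ifit3, both interferon-induced, were 6.61-fold (5.75 to 7.63) and 4.79-fold lower, and the interferon list was lower in 15 of 20 and higher in 0 (median -1.31, percentile 0). Inflammatory myeloid genes were higher in 11 of 17 (median 0.72, percentile 98.4), with Ccl2 3.14-fold and Il1a 2.77-fold. Tumour-associated macrophage genes were higher in 9 of 17 and lower in 2 (median 0.62, percentile 94.7), with Spp1 7.11-fold and Trem2, a lipid receptor, 3.75-fold. The median was 0.53 for osteoclast-regulating cytokines (5 of 11 higher, percentile 81.6), 0.56 for MHC class II (1 of 7 higher, percentile 80.0), 0.39 for hypoxia and glycolysis (6 of 20 higher and 1 lower, percentile 76.9), 0.42 for proliferation (6 of 18 higher, percentile 86.2) and -0.15 for dissociation and stress (3 of 14 lower and 1 higher, percentile 1.73). In osteoclasts, which had 83 and 874 cells, osteoclast genes were higher in 5 of 12 and lower in 0 (median 0.49, percentile 99.9), with Oscar, a co-stimulatory receptor, 4.28-fold and Dcstamp, a fusion protein gene, 2.71-fold higher.

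In neutrophils of scratch-positive, Cxcl3 was 4.33-fold and Lipg 1.80-fold higher than in scratch-negative, and Tnfaip2 was 1.86-fold lower. Interferon genes were lower in 8 of 19 neutrophil members (median -0.56, percentile 0), with Rsad2 3.48-fold. The median was 0.48 for proliferation (6 of 18 higher, percentile 100), 0.15 for hypoxia and glycolysis (1 of 20 higher, percentile 85.5), 0.10 for inflammatory myeloid genes (4 of 17 higher and 2 lower, percentile 56.3), -0.03 for granules (1 of 13 lower, percentile 10.5), -0.28 for activation (percentile 0.06, 4 of 14 lower and 1 higher) and -0.06 for dissociation and stress (2 of 14 lower, percentile 9.07). With equal weight per neutrophil cluster the medians of interferon, proliferation, inflammatory myeloid and activation genes were -0.34, 0.27, 0.41 and -0.03, and with clusters 2 and 6 counted as neutrophils they were -0.17, 0.30, 1.13 and 0.60, with Tnfaip2 at a log2 ratio of 0.22. With at least 1000 genes per cell the log2 ratio of Tnfaip2 was 0.0284 in place of -0.89, and the activation median 0.38. NK-like cells had fewer interferon transcripts (10 of 16 lower, median -1.26, percentile 0), with Isg15 12.1-fold lower on 7 against 156 UMIs, Ifng 4.90-fold lower on 9 against 81 UMIs, and Gzmb 1.66-fold lower. The median of cytotoxic genes was -0.27 (2 of 12 lower, percentile 0.41).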

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

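The single-cluster settings, equal weight per neutrophil cluster, clusters 2 and 6 counted as neutrophils, Scrublet's own calls, cells without a Ptprc UMI and names kept against Ptprc were chosen after the data had been seen. Across all settings 2916 of 2956 log2 ratios of genes and 1660 of 1775 list medians kept their sign. The counts that follow leave out Timp1 and the hypoxia list in fibroblasts, the osteoclast shares and the tumour cell shares of the tumour libraries, which are given below. Beyond counting error, 831 other gene ratios, 564 other medians and 126 other shares moved, 2059, 1124 and 213 did not, and 20 ratios and 35 medians reversed. A change of sign counted as reversed only for ratios that met the rule of size and medians near either end of the random lists. Further changes of sign are not listed as reversals. The cause was not tested unless named. Depth limits the control stroma (48 fibroblasts, 533269 UMIs) and the lymphocytes, such as NK-like cells of scratch-positive (354557 UMIs).

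The order of osteoclast shares held in every setting. In scratch-positive the share was 10.4% of all kept cells, which enlarges the denominator, 24.3% with at least 1000 genes and 27.1% with doublets kept. Tumour cells, in scratch-negative and scratch-positive, were 2.65% and 43.0% of all kept cells, 5.14% and 67.5% with at least 200 genes, 18.2% and 82.3% with doublets kept, 18.3% and 78.2% at resolution 2.0, and 11.0% and 73.4% by marker score. They were 73.3% in scratch-positive with at least 1000 genes and 18.1% in scratch-negative with Scrublet's own calls.

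Timp1 in fibroblasts, scratch-negative over control, had a log2 ratio of 5.03 with TMM factors, 3.99 with osteoblasts joined and 1.69 in cluster 12. Scratch-positive over control it was 3.46 with doublets kept, 4.58 at resolution 2.0, 4.24 in thinned cells, 3.097 with osteoblasts joined and 2.68 in cluster 12. Between the tumour libraries it was -1.13 with doublets kept, -0.87 with Scrublet's own calls, -0.15 at resolution 2.0, -0.87 by marker score, -1.01 with TMM factors, -0.95 with the reduced total, -0.79 as a mean over cells, -0.75 in thinned cells, -0.90 with osteoblasts joined, -1.09 in cluster 27, -1.03 without Ptprc, and reversed to 0.99 in cluster 12. The hypoxia median there was -1.25 with doublets kept, -1.34 with Scrublet's own calls, -1.11 at resolution 2.0, -1.49 with TMM factors, -1.58 in cluster 27, -1.50 without Ptprc, and reversed to 0.19 in cluster 12, where it was 0.13 and 0.11 for scratch-negative and scratch-positive over control.

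Other reversals follow, as log2 values. Cluster 12 alone gave, over control, Mmp13 0.39 (scratch-negative) and 0.89, Vegfa -0.57, Fos 0.42 and stress 0.40 (scratch-positive), and between the tumour libraries Timp3 0.44, Fosb 0.19, osteoclast-regulating cytokines 0.0831 and stress 0.0344. Cluster 27 alone gave osteoblast differentiation 0.39. With osteoblasts joined, over control, Mmp14 was 0.0516 and Fosb -0.0503 (scratch-negative), Vegfa -0.95 and Cxcl10 -2.09 (scratch-positive). Resolution 2.0 gave in fibroblasts Mmp13 0.17, Fos 0.10 and stress 0.17 (scratch-positive over control), Mmp10 -0.51 and osteoblast differentiation 0.73 (between the tumour libraries), and neutrophil activation 0.12. Marker scores gave in osteoblasts Fst 0.85, collagens -0.0831 and stress 0.0977, in fibroblasts Rsad2 -0.85 over control and osteoblast differentiation 0.10 between the tumour libraries, in tumour cells MHC class II 0.36, in NK-like cells Isg15 0.94 for scratch-positive over control, and for scratch-negative over control neutrophil proliferation -0.10 and macrophage stress -0.0742. Neutrophil activation between the tumour libraries was 0.0751 with at least 200 and 0.38 with at least 1000 genes, the latter with Tnfaip2 at 0.0284, and with clusters 2 and 6 counted it was 0.60, with Tnfaip2 at 0.22. Equal weight per neutrophil cluster gave proliferation -0.23 for scratch-negative over control. Collagens in osteoblasts were -0.00797 with at least 200 genes and -0.11 with doublets kept. Cytotoxic genes in NK-like cells were 0.0237 with doublets kept and 0.0171 with Scrublet's own calls. Stress in B-lineage cells (scratch-negative over control) was 0.27 with at least 1000 genes, with mitochondrial UMIs up to 20% and at resolution 2.0, 0.22 by marker score and 0.0665 for members with at least 100 UMIs, and their interferon median -0.24 in thinned cells. Thinned cells gave hypoxia -0.17 in osteoblasts and osteoclast genes -0.0215 in macrophages (scratch-negative over control). Cluster 14 alone gave, over control, osteoclast genes -0.0768, tumour-associated macrophage genes -0.16 and stress -0.00176 (scratch-negative), H2-Ab1 -1.19, osteoclast genes -0.25 and MHC class II -1.30 (scratch-positive), and stress 0.15 between the tumour libraries. Cluster 18 alone gave F13a1 0.18 in scratch-negative over control.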

Other observations

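The comparisons of tumour cells and the tests of explanations were chosen after the results had been seen, except that the test of interferon genes within finer fibroblast clusters was set before its values were seen. Tumour cells of scratch-positive (3620 cells) differed from those of scratch-negative (201 cells) in interferon genes, of which 19 of 20 were lower and 0 higher, with a median log2 ratio of -2.97 (percentile 0). Gbp2, a guanylate-binding protein gene, was 14.1-fold lower and Cxcl10, a chemokine gene that attracts T cells, 13.1-fold lower. Both are among the 10 genes that lead cluster 23, whose epithelial name had the least evidence. It held 148 of the 201 scratch-negative cells and 189 of the 3620 scratch-positive ones. Within it the interferon median was -0.0560, as taken up below. MHC class II genes had a median of -2.71 (7 of 7 lower, percentile 0.01), but at 0.226% to 4.73% of their level in the highest class RNA of other cells is not excluded, and the median was 0.36 with a class given to each cell by marker score. Hypoxia and glycolysis genes were lower in 7 of 20 (median -0.44, percentile 0), with Bnip3 2.69-fold and Hk2 2.44-fold lower, and proliferation genes had a median of 0.09 with 0 of 18 beyond the rule of size (percentile 29.0). Within cluster 23 alone (148 and 189 cells) the medians were -0.0974 for hypoxia and glycolysis, -1.27 for MHC class II and 0.0700 for proliferation, with log2 ratios of -0.68 for Bnip3 and -0.70 for Hk2. The other tumour clusters held at most 23 scratch-negative cells each, so for these lists a different mix of clusters was not separated from a difference within them.

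Interferon list medians were below 0 in scratch-positive against scratch-negative in fibroblasts (14 of 20 lower), monocytes/macrophages (15 of 20), neutrophils (8 of 19), NK-like cells (10 of 16) and tumour cells (19 of 20). Free RNA adds a like number of UMIs to each droplet, so neutrophils, with the fewest interferon UMIs per cell (5.74), limit it, and this limit covers at most 16.8% of the excess per cell in fibroblasts, monocytes/macrophages and tumour cells. In neutrophils the limit is their own level, which exceeds their excess in advance, so it decides nothing there. In NK-like cells the limit was 163% of the excess. Free RNA and a difference within the cells therefore cannot be told apart in neutrophils and NK-like cells. In fibroblasts, monocytes/macrophages and tumour cells the medians stayed at -1.13 or below with every cell thinned to 2000 UMIs. Thinning keeps each gene's expected share of a cell's UMIs, and the classes were not redrawn. It therefore shows only that the weight of deeper cells did not make the medians, and decides nothing else about depth. In fibroblasts and monocytes/macrophages a different mix of clusters is argued against by medians of -0.67 or below within each of clusters 12, 27, 14 and 18. Medians were -0.84 or below in the 2 finer fibroblast clusters with at least 40 cells in both libraries. The other finer cluster (9 and 268 cells) was too small to compare. In tumour cells the median was -0.0560 within cluster 23, but interferon genes lead this cluster, so the value decides nothing and a different mix of clusters and a difference within cells cannot be told apart there, and in fibroblasts and monocytes/macrophages a weaker interferon response on stripped bone and a difference between mice or in handling were not tested and stay open.

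Timp1 in fibroblasts was lower in scratch-positive than in scratch-negative over the whole class. Free RNA is argued against by the level in scratch-negative neutrophils, 0.240% of that in fibroblasts. A different balance of clusters 12 and 27 alone is argued against by the log2 ratio of -1.09 within cluster 27. Among finer clusters with at least 40 cells in both libraries the lowest log2 ratio was 0.64, with 661 against 1316 CPM (193 and 110 cells) and 6561 against 10237 (340 and 44 cells) in scratch-negative and scratch-positive. In the other finer cluster (9 and 268 cells) Timp1 was at 4088 and 1894 CPM, which goes against a mix of clusters alone on few cells, and the clusters were drawn with the same genes, so a mix of finer clusters and a difference within them cannot be told apart.

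The osteoclast-like share of immune cells was highest in scratch-positive. Fewer neutrophils in the denominator are argued against by the share among osteoclasts and monocytes/macrophages together, which was 4.74 times that of scratch-negative. Free RNA is argued against by Ctsk in neutrophils, at 0.442% of its level in osteoclasts, though Ctsk alone was tested and it also helped to name the class. Doublets of other classes, as the source of the whole cluster, are argued against by the osteoclast list, since a doublet lies between its parents and 8 of 11 genes were above their level in every other cluster compared, unnamed ones included, with a median of 4.247 times the highest, though of the 3 genes that were not used to name the class only Tnfrsf11a was above and Itgb3 and Car2 were not. In scratch-positive the osteoclast share was higher still with doublets kept, as given above, so doublets as a part of this cluster are not excluded. More osteoclasts on stripped bone and a freer release of cells from scratched bone during digestion were not tested and stay open.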
